A study of Mus musculus with 18 samples.

How the data were processed

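Total RNA from cultured mouse mast cells of either Dnmt3a genotype was measured on 18 Illumina bead arrays. Each group of genotype and condition (untreated, 4 h or 24 h of IgE and antigen) had 3 arrays, 1 from each of 3 cultures, and the groups, culture numbers and slides were taken from the sample labels. Per the labels' protocols, biotin-labelled cRNA was made with an Ambion amplification kit for Illumina arrays. The deposited table of non-normalised values holds the intensity of each probe on a linear scale, with no background subtraction and no normalisation between arrays. The authors' second table holds log2 values, which differed from quantile normalised log2 intensities of the first table by at most 0.000556. Its median was 6.92 on every array. Scanner software, summarisation and the authors' tool are not given in the sources used here.

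The intensities were background corrected by normexp with an offset of 50, quantile normalised and put on the log2 scale, in R 4.3.3 with limma 3.58.1. The neqc method had been planned, but the files hold no detection p-values or control probes, so normexp was fitted to each array's own signals. For the same reason detection was taken from 1504 probes for 1249 olfactory and vomeronasal receptor genes, which mast cells are not known to express. A probe was called detected on an array when at most a share of 0.01 of these probes had a signal as high, and it was kept when detected on at least 3 arrays. This rule replaced one based on the mode of each array's signals after exploratory fits had been seen, and the mode-based rule is kept as an alternative. Detection limits ran from 107 to 222 and lowest signals from 73.0 to 107. Of 45281 probes 16669 were kept, among them 30 receptor probes.

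Gene names came from the gene symbols in the files, where 34885 probes had 1 symbol, 18 had several and 10378 had none in the table. Entrez identifiers of 34807 probes matched the GRCm38.p6 gene table, and 0 symbols changed. That table was used only for names and for which genes neighbour each other, and no coordinates were taken from it. Of the kept probes 14073 had 1 symbol. They gave 8985 genes, each represented by its probe with the highest mean, and the 2596 kept probes without a single gene were tested apart. An Illumina probe covers a short stretch of a transcript, so that other transcript forms were not measured.

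All 18 arrays were fitted in limma with 6 group means and no block, with eBayes moderation, two-sided tests and Benjamini-Hochberg adjustment over the genes of a comparison at an adjusted p of 0.05. Comparisons were 4 h and 24 h against untreated in each genotype, 24 h against 4 h in wild-type cells, knockout against wild type in each condition, the knockout response minus the wild-type response at 4 h and 24 h, and knockout against wild type on the mean of each culture's 3 arrays. Gene lists with at least 5 measured genes were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. There were 21 pathway lists and 11 marker lists of other cell types, and 25 of the 32 could be tested. The tests, the lists, the rule for named genes and the settings listed first below were fixed before the data were examined. Named genes are the 10 largest rises and the 10 largest falls among genes past the threshold with the same direction in each of the 3 cultures (or within each of the 3 slides, for genotype). To these come list members past the threshold and the 2 members of each list with the largest change. Where fewer than 5 genes passed, the 5 with the smallest p were named as not past the threshold. Csf2 and the genes named for differences in response fall under the rule for lists or for few genes. The pipeline was tested on simulated data for the 4 h comparison in wild-type cells over 8985 genes. Of 50 genes changed by each size it recovered 5 at a log2 change of 0.5, 28 at 1, 49 at 2 and 49 at 3, with 5 unchanged genes called.

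Arrays read as 1 culture had deviations from the group means that correlated with 0.134 to 0.625 (median 0.361, all 18 pairs over 0.1). Pairs across genotypes on 1 slide had a median of 0.328 (22 of 27 over 0.1) and pairs on other slides −0.172 (90 pairs). On each slide the former were higher within a condition (0.181 to 0.751) than across (−0.189 to 0.450), which no block models. Culture and slide were not told apart. No array was a copy of another (highest correlation 0.985).

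The other settings tried were no background correction, median scaling, cyclic loess, the authors' values, no filter on dim probes, every kept probe, the slide as a block, a replicate block (the culture), the culture as a random block, fits to the compared groups alone, array weights, and each culture left out in turn. Chosen after seeing the data were the mode-based detection, fits without the 4 h array of wild-type culture 9 or the 24 h array of knockout culture 6, and slides 1 and 2 alone. Sequence-level differences between the mice and promoter methylation were not analysed here.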

Results

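Messenger RNA was measured with Illumina mouse bead arrays in mast cells from wild-type mice and from mice lacking Dnmt3a, an enzyme that sets DNA methylation de novo. The cells were resting or had been stimulated through IgE and its antigen for 4 h or 24 h. There were 18 arrays in 6 groups of 3, from 3 wild-type and 3 knockout cultures of 5 weeks from female mice. The labels give only numbers, which are read here as separate cultures, and they do not say whether a culture came from 1 mouse. Every culture gave 1 array per condition. Slide 1 held wild-type culture 6 and knockout culture 3, slide 2 wild-type 8 and knockout 4, and slide 3 wild-type 9 and knockout 6. Median probe signals ran from 93.4 to 159 and the highest signals from 22893 to 34871. Between 28.7% and 33.8% of the probes on an array were above its detection limit, and 8985 genes were tested. Few arrays limit the precision, and p-values rest on the spread between cultures within groups. Except for culture means, they take a culture's arrays as independent (correlation 0.291) and ignore pairing over time. Each ± after a log2 fold change is the standard error from limma, with 3 arrays per group. Where a gene was above the limit on no array of the lower group, its fold is given against that limit as "at least". Where it was above the limit on some arrays of that group, their number follows the log2 change as "1 of 3" or "2 of 3", and the size then rests partly on signals below the limit. Over all comparisons 76 list results passed with a preset correlation between genes, and 2 (germline genes) also with an estimated one. With no block fitted, the estimate can take in slide and culture shifts.

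The targeted gene could not be used to check the genotype labels. The arrays carry 3 Dnmt3a probes, and 0 of 18 arrays had any of them above its detection limit. Their signals were between 83.1 and 150, or 51.0% to 87.1% of the limit on the same array, in wild-type and knockout cells. Dnmt3a was therefore not among the genes tested in any comparison.

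The first comparison asked how wild-type mast cells respond to 4 h of IgE and antigen. Ccl3, which attracts monocytes and other leukocytes, rose 69.4-fold (log2 6.12 ± 0.70, adjusted p = 0.000868), from a mean log2 intensity of 7.55 ± 0.36 (SD, n = 3) to 13.67 ± 1.47. Ccl7, another monocyte attractant, rose 33.6-fold (log2 5.07 ± 0.44, adjusted p = 4.11e-05). Ccl1 rose at least 52.8-fold (adjusted p = 0.00552). The type 2 cytokine Il13 rose 7.76-fold (log2 2.96 ± 0.50, adjusted p = 0.0106).

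Of 14 measured chemokines, 5 rose, 0 fell and 9 were not past the threshold over all genes at 4 h, and 6 rose when adjusted over the list alone. Besides Ccl1, Ccl3 and Ccl7 these were Ccl4 (log2 3.60 ± 0.48) and Ccl2 (1.94 ± 0.30). The list shifted upwards with a median log2 change of 1.48 (adjusted p = 9.14e-10), and with 1.89, 1.54 and 0.54 in cultures 6, 8 and 9. Its adjusted p = 0.271 with an estimated correlation. Among 24 cytokines, Il13, Tnf (2.10 ± 0.48, 2 of 3) and the macrophage growth factor Csf1 (1.89 ± 0.43) rose, 0 fell, and 15 rose when adjusted over the list alone. The cytokine median was 1.04 (adjusted p = 2.2e-09; cultures 1.11, 1.06 and 0.71), with adjusted p = 0.284 with an estimated correlation. Csf2, the granulocyte-macrophage growth factor, was at least 8.99-fold higher and not past the threshold (adjusted p = 0.069). It was past it with the slide as a block (adjusted p = 0.0208) and with the replicate block (adjusted p = 0.0289).

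Of 27 immediate early genes and MAP kinase phosphatases, the zinc finger factors Egr2 (3.84 ± 0.63, 2 of 3) and Egr3 (2.83 ± 0.54) rose, 0 fell, and 5 rose when adjusted over the list alone. The list median was 0.33 (adjusted p = 4.03e-05; cultures 0.62, 0.45 and 0.19), with adjusted p = 0.284 with an estimated correlation. Of 26 NF-kB targets and feedback regulators, Nfkbid (1.72 ± 0.33), Relb (at least 1.63-fold) and the inhibitor Nfkbib (0.65 ± 0.15) rose and 0 fell, against 7 higher and 1 lower when adjusted over the list alone. Their median was 0.53 (adjusted p = 0.00172; cultures 0.64, 0.54 and 0.09), with adjusted p = 0.356 with an estimated correlation. Other genes with large rises were Fxyd6 (3.35 ± 0.67), which encodes a regulator of the sodium pump, the retinoic acid binding protein gene Crabp2 (at least 5.28-fold), Pdcd1lg2 (2.70 ± 0.46), which encodes a ligand of the inhibitory receptor PD-1, and the growth factor gene Igf2 (2.11 ± 0.33, 1 of 3).

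In wild-type cells at 4 h all 27 measured ribosome production genes had positive changes, 3 rose over all genes (Rrp9 1.09 ± 0.21, Rrs1 1.0 ± 0.21 and Nop2 0.98 ± 0.21), 0 fell, and 17 rose when adjusted over the list alone. The median was 0.58 (adjusted p = 6.45e-12; cultures 0.50, 0.89 and 0.28), with adjusted p = 0.284 with an estimated correlation. Among 18 cholesterol synthesis genes, Hsd17b7 rose (2.02 ± 0.46), 0 fell, and 5 rose when adjusted over the list alone. That list had a median of 0.59 (adjusted p = 4.03e-05), with 1.20, 0.70 and −0.13 in cultures 6, 8 and 9, and adjusted p = 0.391 with an estimated correlation. Of 28 genes of the unfolded protein and amino acid stress response, 0 passed over all genes or when adjusted over the list alone, while the list shifted upwards (median 0.32, adjusted p = 0.0119; cultures 0.36, 0.29 and −0.00). Its adjusted p = 0.581 with an estimated correlation, and 0.117 without wild-type culture 6.

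Other genes fell. The largest falls were in Ypel3 (−2.72 ± 0.49, adjusted p = 0.0142), a gene linked to growth arrest, Pigz (−2.62 ± 0.60), N4bp2l1 (−1.98 ± 0.44, 2 of 3) and Tbc1d8 (−1.91 ± 0.45). Both low-affinity IgG receptor genes fell, Fcgr3 with −1.88 ± 0.28 (adjusted p = 0.00569) and the inhibitory Fcgr2b with −1.68 ± 0.29 (adjusted p = 0.0106), as did the cytokine gene Il16 (−1.81 ± 0.27, adjusted p = 0.00569). Of 26 interferon-stimulated genes, Gbp2 (−1.64 ± 0.34) and Parp14 (−1.20 ± 0.24, 1 of 3) fell, 0 rose, and 6 fell when adjusted over the list alone. Their median was −0.36 (adjusted p = 0.000496; cultures −0.21, −0.54 and −0.32), with adjusted p = 0.284 with an estimated correlation. The list of mast cell receptors, regulators and mediator enzymes shifted downwards (median −0.31, adjusted p = 0.0438; cultures −0.36, −0.31 and −0.12), with 0 of 29 genes past the threshold over all genes and 2 lower when adjusted over the list alone. With an estimated correlation its adjusted p = 0.581. The 42 cell cycle and DNA replication genes shifted downwards too (median −0.41, adjusted p = 0.0415; cultures −0.48, −0.60 and −0.12), with 0 genes past the threshold over all genes or over the list alone and adjusted p = 0.724 with an estimated correlation. Without wild-type culture 6 the receptor list had adjusted p = 0.115 and the cell cycle list 0.167.

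The remaining 15 tested lists were not past the threshold in wild-type cells at 4 h. Among them were granule proteases (median −0.06, adjusted p = 0.954), signalling components of the IgE receptor (−0.10, 0.46), eicosanoid synthesis (−0.45, 0.388), exocytosis genes (−0.11, 0.216; Rab3d fell by 1.03 on the log2 scale), the DNA methylation machinery (−0.13, 0.395) and imprinted genes (−0.07, 0.6; Igf2 rose). Lysosome genes had a median of −0.26 (adjusted p = 0.0536), with falls of Psap (−0.88 ± 0.20) and Glb1 (−0.87 ± 0.20; another probe of Glb1 had the opposite sign and was not past the threshold). Basophil markers (0.64, 0.259; Csf1 rose) and stem and progenitor markers (−0.04, 0.891) also stayed on that side. These 9 lists were not past the threshold in any other comparison either. Medians were 0.06 for inhibitors of cytokine and receptor signalling (adjusted p = 0.45; Sla rose by 1.18 and Fcgr2b fell), −0.08 for germline genes (0.677), −0.01 for glycolysis (0.45), 0.05 for oxidative phosphorylation (0.395), −0.31 for macrophage markers (0.412) and 0.27 for erythroid markers (0.395). Marker lists with fewer than 5 measured genes were not tested. Measured were 4 of 20 neutrophil, 0 of 10 eosinophil, 4 of 18 T and NK cell, 2 of 13 B cell, 2 of 14 dendritic cell, 4 of 12 megakaryocyte and platelet and 0 of 12 fibroblast markers.

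**Figure D1:**
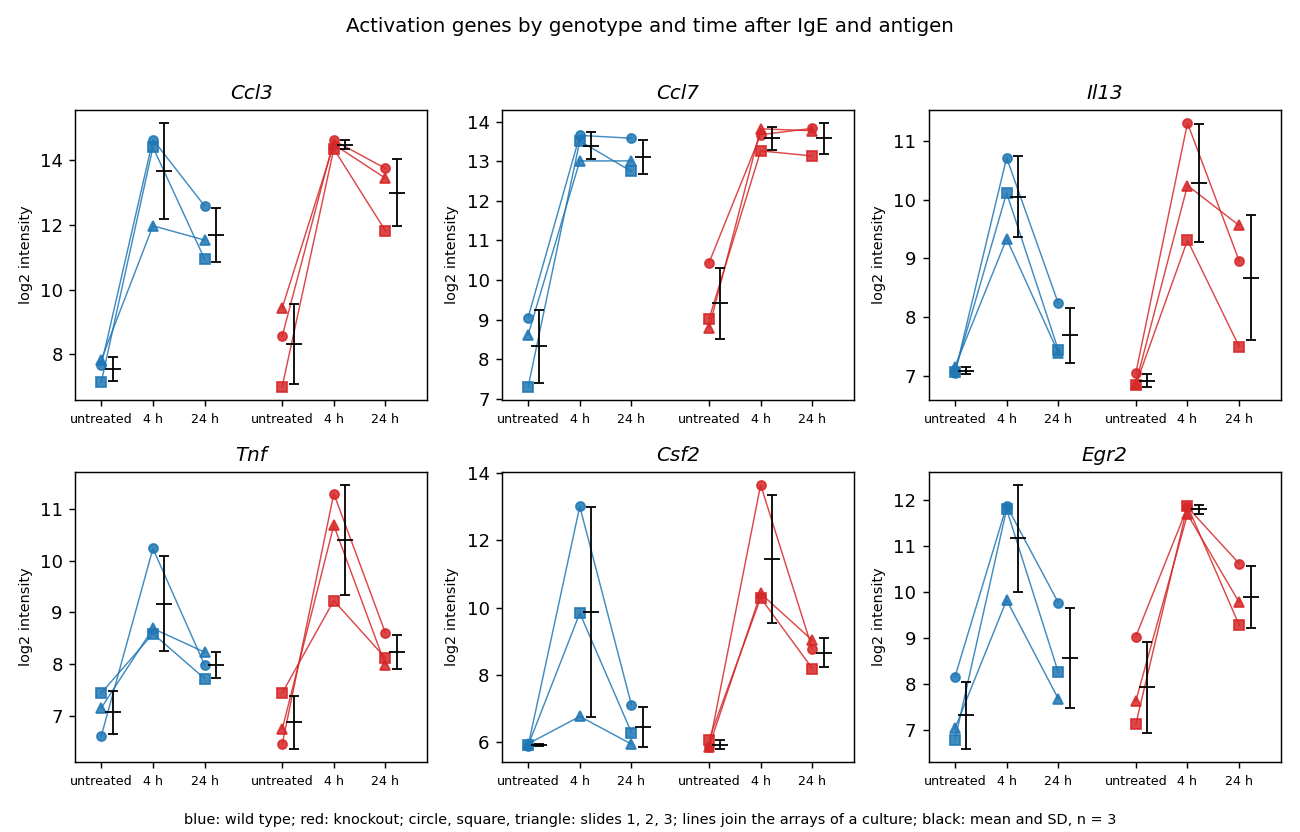
Log2 intensity (vertical axis) of Ccl3, Ccl7, Il13, Tnf, Csf2 and Egr2 without stimulation and after 4 h and 24 h (horizontal axis) in wild-type (blue) and knockout (red) cultures; symbols are single arrays with circles, squares and triangles for slides 1, 2 and 3, lines join a culture, and black marks are means ± SD (n = 3). Ccl3 went from 7.55 to 13.67 in wild-type cells at 4 h and from 8.33 to 14.48 in knockout cells.

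In all, 164 genes passed limma's test at 4 h in wild-type cells, 80 higher and 84 lower, and 95 of the 164 changed at least 2-fold. The slide as a block gave 873 genes (415 higher, 458 lower) and the replicate block gave 769. With the slide block 10 cytokines, 8 immediate early genes, 8 NF-kB genes and 11 ribosome production genes were higher and 8 interferon-stimulated genes were lower. Median scaling gave 46 genes with 39 higher and 7 lower, so that the share of higher genes was 84.8% against 48.8%. Without a culture the count was 23 (wild-type 6), 1 (wild-type 8), 326 (wild-type 9), 95 (knockout 3) or 67 (knockout 4), and it was 966 without the 4 h array of wild-type culture 9. That culture had a smaller 4 h response than the others, with a slope of 0.455 on the knockout cells' response against 1.0 and 1.02 in cultures 6 and 8.

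The next comparison asked which changes were present in wild-type cells after 24 h. Ccl7 was still 27.7-fold above untreated cells (log2 4.79 ± 0.44, adjusted p = 9.12e-05) and Ccl3 was 17.5-fold above them (4.13 ± 0.70, adjusted p = 0.0249). The C-type lectin receptor genes Clec4n (3.34 ± 0.37, 2 of 3, adjusted p = 0.000594), Clec10a (1.34 ± 0.28) and Clec4d (1.14 ± 0.25, 2 of 3) rose. Clec4n, which encodes dectin-2, went from a mean log2 intensity of 6.75 ± 0.15 (SD, n = 3) to 10.09 ± 0.40. The histone gene H2ac8 (2.0 ± 0.35, 2 of 3), the glycine metabolism gene Gcat (1.78 ± 0.39), the adaptor gene Sla (1.38 ± 0.21), Gstt3 (1.28 ± 0.26) and Tsc22d1 (1.18 ± 0.25) rose as well.

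Falling genes at 24 h in wild-type cells included Fgl2 (−1.82 ± 0.37), Ctla2b (−1.78 ± 0.34) and Ctla2a (−1.51 ± 0.33), which encode cysteine protease inhibitor-like proteins, the selenium carrier gene Selenop (−1.72 ± 0.35), Stard5 (−1.61 ± 0.28), the glutamine synthetase gene Glul (−1.49 ± 0.29) and Il16 (−1.44 ± 0.27). Fam155a (−1.64 ± 0.36), Rsph9 (−1.58 ± 0.34) and Sec14l2 (at least 2.01-fold lower) fell too. Cd200r3, an activating receptor gene of mast cells and basophils, fell by 0.86 on the log2 scale.

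Of the 14 chemokines, Ccl7 and Ccl3 rose at 24 h in wild-type cells, 0 fell, and 4 rose when adjusted over the list alone. The list median was 0.29 (adjusted p = 0.00489; cultures 0.59, 0.03 and 0.37), with adjusted p = 0.468 with an estimated correlation. All 42 cell cycle genes had positive changes, with a median of 1.05 (adjusted p = 7.1e-12) and with 0.02, 1.58 and 1.57 in cultures 6, 8 and 9. None passed singly, and adjusted p = 0.39 with an estimated correlation. The mitotic topoisomerase gene Top2a had 1.81 ± 0.61 (adjusted p = 0.168). Cholesterol synthesis genes had a median of 0.64 (adjusted p = 4.33e-08; cultures 1.42, 0.55 and 0.30), 0 passed over all genes and 5 rose when adjusted over the list alone, and adjusted p = 0.39 with an estimated correlation.

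At 24 h in wild-type cells the unfolded protein and amino acid stress list had a median of 0.38 (adjusted p = 0.000173; cultures 0.52, 0.33 and 0.40), with 0 genes past the threshold over all genes, 7 higher when adjusted over the list alone and adjusted p = 0.39 with an estimated correlation. The glycolysis and hypoxia list had a median of 0.38 (adjusted p = 0.00744; cultures 0.22, 0.13 and 0.54), with adjusted p = 0.468 with an estimated correlation and 0.179 without wild-type culture 9. For oxidative phosphorylation the median was 0.21 (adjusted p = 0.000147; cultures 0.17, 0.29 and 0.16), with adjusted p = 0.39 with an estimated correlation. Neither of these lists had a gene past the threshold over all genes or over the list alone. Median scaling put the median of all genes in this comparison at 0.26, and with it the chemokine and glycolysis lists were not past the threshold (adjusted p = 0.0815 for both). The chemokine median was 0.03 with no filter on dim probes (25 genes, adjusted p = 0.23) and 0.06 with mode-based detection (20 genes, 0.119). The cytokine list had a median of 0.18 (adjusted p = 0.0595), and it was past the threshold with the slide block (adjusted p = 0.0337) and the replicate block (adjusted p = 0.0164). The 5 macrophage markers had a median of −1.05 (adjusted p = 0.0873, 0.0337 with the slide block and 0.0445 with the replicate block).

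At 24 h, 62 genes passed limma's test in wild-type cells, 25 higher and 37 lower. There were 471 with the slide block (199 higher, 272 lower) and 418 with the replicate block. With the slide block 4 chemokines, 4 cell cycle genes, 3 cholesterol synthesis genes and 3 unfolded protein response genes were higher. Median scaling gave 19 genes, 18 higher and 1 lower, or 94.7% higher against 40.3%. Leaving out 1 culture gave 17 genes without knockout 4, 14 without knockout 6, 2 without wild-type 6, 1 without wild-type 8 and 1 without wild-type 9.

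A direct comparison of 24 h with 4 h in wild-type cells asked which part of the response was transient. Il13 fell by 2.36 on the log2 scale (SE 0.50, adjusted p = 0.019), Egr2 by 2.60 (SE 0.63, adjusted p = 0.0306) and Ccl4 by 2.21 (SE 0.48, adjusted p = 0.021). Cd274, which encodes the PD-1 ligand PD-L1, went from a mean log2 intensity of 11.29 ± 0.45 (SD, n = 3) to 9.79 ± 0.28 (adjusted p = 0.00929). Top2a went from 7.16 ± 0.78 to 9.73 ± 0.62 (2 of 3, adjusted p = 0.0291).

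Of the 42 cell cycle and DNA replication genes, 7 rose from 4 h to 24 h, 0 fell, and 31 rose when adjusted over the list alone. Examples are Cdca8 (2.64 ± 0.71) and Bub1b (2.57 ± 0.71, 2 of 3), which act at the kinetochore, Top2a, and the replication gene Mcm10 (2.21). The list median was 1.38 (adjusted p = 5.45e-14; cultures 0.70, 2.26 and 1.47), with adjusted p = 0.302 with an estimated correlation. Outside the list, the mitotic kinase gene Pbk (2.92 ± 0.79, 2 of 3), the cohesin acetyltransferase gene Esco2 (2.90 ± 0.55, 1 of 3), Spag5 (2.62 ± 0.67, 2 of 3), Spc25 (2.62 ± 0.65, 2 of 3) and Gtse1 (2.55 ± 0.56, 2 of 3) rose. Mrvi1 (2.77 ± 0.55) and 3110040M04Rik (2.70 ± 0.74, 1 of 3) rose too. Interferon-stimulated genes had a median of 0.32 (adjusted p = 0.00598; cultures 0.49, 0.20 and 0.19), with rises of Psmb9 (1.31 ± 0.27), Ifi47 (1.13) and the peptide transporter gene Tap1 (at least 1.27-fold), 0 falls, 4 rises when adjusted over the list alone, and adjusted p = 0.309 with an estimated correlation. Oxidative phosphorylation genes had a median of 0.18 (adjusted p = 0.0206; cultures 0.00, 0.40 and 0.11), with 0 genes past the threshold over all genes or over the list alone and adjusted p = 0.506 with an estimated correlation. With median scaling, which put the median of all genes at 0.14, that list had adjusted p = 0.196, and it had 0.369 without wild-type culture 8 and 0.0596 without wild-type culture 9.

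Of 24 cytokines, Il13 and Il6 (−1.65 ± 0.46) fell from 4 h to 24 h and 0 rose, against 11 lower and 1 higher when adjusted over the list alone. The median was −0.68 (adjusted p = 0.000265; cultures −0.93, −0.88 and −0.19), with adjusted p = 0.414 with an estimated correlation. Among chemokines, Ccl4 and Ccl2 (−1.22 ± 0.30) fell, 0 rose, and 5 fell when adjusted over the list alone (median −0.84, adjusted p = 0.000205; cultures −0.75, −1.34 and −0.25), with adjusted p = 0.302 with an estimated correlation. Of 27 immediate early genes, Egr2, Csrnp1 (−1.93 ± 0.52), Gadd45b (−1.69 ± 0.41, 1 of 3) and Fosl2 (−1.17) fell and 0 rose, against 6 lower and 1 higher when adjusted over the list alone. Their median was −0.56 (adjusted p = 6.97e-05; cultures −0.69, −0.43 and −0.32), with adjusted p = 0.302 with an estimated correlation. In the NF-kB list 5 of 26 genes fell and 0 rose, among them Plaur (−1.29), Nfkbid (−1.26) and Relb (at least 1.63-fold lower), with 11 lower and 1 higher when adjusted over the list alone. That list had a median of −0.72 (adjusted p = 5.88e-05; cultures −0.71, −0.80 and −0.35), with adjusted p = 0.302 with an estimated correlation. Of 27 ribosome production genes 6 fell over all genes (Rrp12 −1.15 ± 0.24 and Rrp9 −1.04 among them), 14 fell when adjusted over the list alone, and 0 rose (median −0.61, adjusted p = 7.1e-09; cultures −0.95, −0.49 and −0.39). With an estimated correlation the adjusted p = 0.302.

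Further falls from 4 h to 24 h were in the cholesterol hydroxylase gene Ch25h (at least 4.61-fold lower), Crabp2 (at least 5.27-fold lower), Emp1 (−2.46 ± 0.58), Dhx34 (−2.29 ± 0.40), Chst11 (−2.15 ± 0.50), Cryba4 (−2.11 ± 0.36, 1 of 3) and the carbonic anhydrase gene Car2 (−1.74 ± 0.48). Signalling genes that fell were Cish (−1.24 ± 0.24), Lat (−0.92) and Gab2 (at least 1.14-fold lower), the last pair acting downstream of the IgE receptor. Inhibitors of cytokine and receptor signalling had a list median of −0.20 (adjusted p = 0.0651, and 0.0336 with the replicate block). Fcgr2b (1.59 ± 0.29), the secretion genes Rab3d (1.18) and Unc13d (1.0), Grn (0.99), Mbd4 (at least 1.22-fold), Ehmt2 (0.63), Pdia4 (0.72) and Tuba3b (1.24) rose.

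The comparison of 24 h with 4 h had 491 genes past the threshold in limma, 275 higher and 216 lower. The slide block gave 1690 (900 higher, 790 lower) and the replicate block 1606. With the slide block 25 cell cycle genes were higher, and 10 cytokines, 10 NF-kB genes, 7 immediate early genes, 5 chemokines and 14 ribosome production genes were lower. With median scaling there were 44 genes, 36 higher and 8 lower, or 81.8% higher against 56.0%. Leaving out knockout culture 4 gave 230 genes, wild-type culture 6 gave 8 and wild-type culture 8 gave 1, and 1413 passed without the 4 h array of wild-type culture 9.

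Knockout cells were compared with their own untreated cultures to describe their response at 4 h. The same chemokines led it. Ccl3 rose 71.0-fold (log2 6.15 ± 0.70, adjusted p = 0.000404), and Ccl1 (6.35 ± 0.86, 1 of 3, adjusted p = 0.00136) and Tnf (3.53 ± 0.48, 1 of 3, adjusted p = 0.00136) rose too. Csf2 rose at least 26.4-fold (adjusted p = 0.0282), from a mean log2 intensity of 5.92 ± 0.13 (SD, n = 3) to 11.46 ± 1.91.

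In knockout cells at 4 h, 6 of 24 cytokines rose, 0 fell and 18 rose when adjusted over the list alone. They were Csf2, Tnf, Il13 (3.35 ± 0.50), Csf1 (2.89 ± 0.43), the lymphotoxin gene Lta (2.30 ± 0.40) and Tnfsf14 (1.89 ± 0.42). The list median was 1.51 (adjusted p = 1.21e-16; cultures 3, 4 and 6 with 1.98, 1.55 and 1.31), with adjusted p = 0.0893 with an estimated correlation. Of 14 chemokines 6 rose and 0 fell, with 8 higher when adjusted over the list alone: besides Ccl1 and Ccl3 these were Ccl7 (4.17 ± 0.44), Ccl4 (3.29 ± 0.48), Ccl2 (2.25 ± 0.30) and Ccl17 (1.97 ± 0.36, 2 of 3). Their median was 2.11 (adjusted p = 1.92e-12; cultures 2.51, 1.66 and 1.91), with adjusted p = 0.0643 with an estimated correlation. Of 27 immediate early genes, Egr3 (4.21 ± 0.54, 2 of 3), Egr2 (3.87 ± 0.63), the phosphatase gene Dusp2 (2.92 ± 0.58, 2 of 3) and Rcan1 (1.43 ± 0.15), an inhibitor of calcineurin, rose and 0 fell, with 15 higher when adjusted over the list alone. The median was 0.58 (adjusted p = 6.63e-11; cultures 1.16, 0.55 and 0.57), with adjusted p = 0.0643 with an estimated correlation. Of 26 NF-kB genes 7 rose and 0 fell, among them the survival gene Bcl2a1d (at least 4.55-fold), Nfkbid (2.08 ± 0.33), Rel (1.25, 1 of 3) and Nfkb2 (1.05), against 9 higher and 2 lower when adjusted over the list alone. That median was 0.69 (adjusted p = 6.19e-07; cultures 0.94, 0.75 and 0.48), with adjusted p = 0.0893 with an estimated correlation.

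Ribosome production genes had a median of 0.35 in knockout cells at 4 h (adjusted p = 3.38e-06; cultures 0.42, 0.34 and 0.29), with Rrp9 higher (1.01), 0 lower, 3 higher when adjusted over the list alone and adjusted p = 0.474 with an estimated correlation. Cholesterol synthesis genes had a median of 0.41 (adjusted p = 0.000833; cultures 1.07, 0.33 and −0.06) and unfolded protein response genes one of 0.25 (adjusted p = 0.008; cultures 0.66, 0.23 and 0.05). Both had 0 genes past the threshold over all genes or over the list alone, and both had adjusted p = 0.474 with an estimated correlation and 0.274 without knockout culture 3. The mast cell receptor list (median −0.21, adjusted p = 0.0394; cultures −0.39, −0.30 and −0.31) had 0 genes past the threshold over all genes and 2 higher and 5 lower when adjusted over the list alone. Its adjusted p was 0.0539 with the slide block, 0.0509 with the replicate block, 0.129 with median scaling, 0.0738 without knockout culture 3, 0.0801 without knockout culture 6, and adjusted p = 0.474 with an estimated correlation. The cell cycle list (median −0.34, adjusted p = 0.0473; cultures −0.27, −0.59 and −0.16) had 0 genes past the threshold over all genes or over the list alone, adjusted p = 0.0583 with the slide block, 0.245 without knockout culture 4, 0.057 without wild-type culture 9, and adjusted p = 0.694 with an estimated correlation. Other rises were in Zbtb32 (3.54 ± 0.78, 1 of 3), Crabp2 (at least 8.33-fold) and the hypoxia gene Ndrg1 (3.44 ± 0.69). Il16 (−1.79 ± 0.27), Fcgr2b (−1.47 ± 0.29), Fcgr3 (−1.35 ± 0.28), Snx14 (−1.38 ± 0.24), Pcmtd2 (−1.20) and Ccdc117 (−1.11) fell.

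In knockout cells at 4 h 73 genes passed limma's test, 57 higher and 16 lower. With the slide block there were 499 (285 higher, 214 lower), and 415 with the replicate block, and 14 cytokines, 11 immediate early genes and 10 NF-kB genes were higher with the slide block. Median scaling gave 98.1% higher against 78.1%. Without knockout cultures 3, 4 and 6 the counts were 16, 22 and 28, without wild-type cultures 8 and 9 they were 25 and 154, and 251 genes passed without the 4 h array of wild-type culture 9, which enters through the shared spread.

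After 24 h, knockout cells still had high levels of Ccl1, at log2 4.70 ± 0.86 above untreated (1 of 3, adjusted p = 0.0345), Ccl3 at 4.67 ± 0.70 (adjusted p = 0.0102) and Ccl7 at 4.17 ± 0.44 (adjusted p = 0.000528). Clec4n rose by 2.82 ± 0.37 (2 of 3, adjusted p = 0.00345) and Sla by 1.95 ± 0.21 (adjusted p = 0.000528). Also higher were Gm4847 (at least 4.96-fold), the matricellular gene Ccn4 (at least 4.43-fold), the galectin gene Lgals7 (2.43 ± 0.48, adjusted p = 0.0497), the succinate receptor gene Sucnr1 (at least 2.35-fold) and Gstt3 (1.54 ± 0.26). Genes that fell were Pxdc1 (−1.79 ± 0.29), the protein kinase D gene Prkd3 (−1.43 ± 0.26, 2 of 3), Plscr5 (−1.04, 2 of 3), the inositol phosphate kinase gene Ip6k1 (−0.98), Crtc3 (−0.97), Smpdl3a (adjusted p = 0.0365; above the limit on 2 of 3 untreated arrays and 0 of 3 at 24 h, so with no size) and Wdr92 (−1.07; another probe had the opposite sign).

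Of 14 chemokines, 3 rose in knockout cells at 24 h, 0 fell and 6 rose when adjusted over the list alone (median 0.69, adjusted p = 1.43e-05; cultures 0.70, 0.12 and 1.15), with adjusted p = 0.31 with an estimated correlation. The cytokine list had a median of 0.71 (adjusted p = 2.93e-06; cultures 0.59, 0.32 and 0.92), with 0 of 24 past the threshold over all genes, 3 higher when adjusted over the list alone and adjusted p = 0.371 with an estimated correlation. Cholesterol synthesis genes had a median of 0.76 (adjusted p = 7.76e-08; cultures 1.22, 0.50 and 0.65), with 0 past the threshold over all genes, 10 of 18 higher when adjusted over the list alone and adjusted p = 0.31 with an estimated correlation. Glycolysis genes had a median of 0.48 (adjusted p = 4.02e-06; cultures 0.27, 0.47 and 0.71; adjusted p = 0.31 with an estimated correlation) and unfolded protein response genes one of 0.47 (adjusted p = 5.32e-05; cultures 0.68, 0.16 and 0.51; adjusted p = 0.371 with an estimated correlation). Cell cycle genes had a median of 0.57 (adjusted p = 5.32e-05) with −0.05, 0.34 and 1.5 in cultures 3, 4 and 6, adjusted p = 0.551 without culture 6, and adjusted p = 0.71 with an estimated correlation. For oxidative phosphorylation the median was 0.14 (adjusted p = 0.018; cultures 0.19, 0.02 and 0.23), with adjusted p = 0.708 with an estimated correlation, 0.0554 without knockout culture 3 and 0.261 without knockout culture 6. These 4 lists had 0 genes past the threshold over all genes or over the list alone. The 5 erythroid markers had a median of 0.41 (adjusted p = 0.018; cultures 0.09, 0.55 and 0.75), with 0 past the threshold over all genes and 2 higher when adjusted over the list alone, and adjusted p = 0.31 with an estimated correlation, 0.0591 without knockout culture 4 and 0.11 without knockout culture 6. The globin gene Hbb-bt had 2.99 ± 0.87 (adjusted p = 0.135) and the erythroid factor Klf1 was at least 1.64-fold higher (adjusted p = 0.0925).

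In knockout cells at 24 h 22 genes passed limma's test, 14 higher and 8 lower, and 347 passed with the slide block (181 higher, 166 lower) or 277 with the replicate block. With the slide block 6 chemokines, 5 cytokines and 3 cholesterol synthesis genes were higher. The share of higher genes was 63.6%, against 91.7% with median scaling, which put the median of all genes at 0.14, 73.7% with cyclic loess, and 81.8% without background correction or with the authors' values. Without knockout cultures 3, 4 and 6 there were 6, 12 and 4 genes and without wild-type culture 8 there were 8, and 3 passed without the 24 h array of knockout culture 6.

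The responses of both genotypes went the same way across genes, with no array shared between them. At 4 h the log2 changes correlated with Pearson's r = 0.860 and Spearman's rho = 0.787 over 8985 genes, which are not independent replicates. Of 164 genes called in wild-type cells, 162 had the same sign in knockout cells, as did 73 of 73 the other way round, and 42 were called in both (1.33 expected from independent lists). At 24 h r was 0.763 and rho 0.702, 62 of 62 and 22 of 22 had the same sign, and 10 were called in both (0.152 expected).

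**Figure D2:**
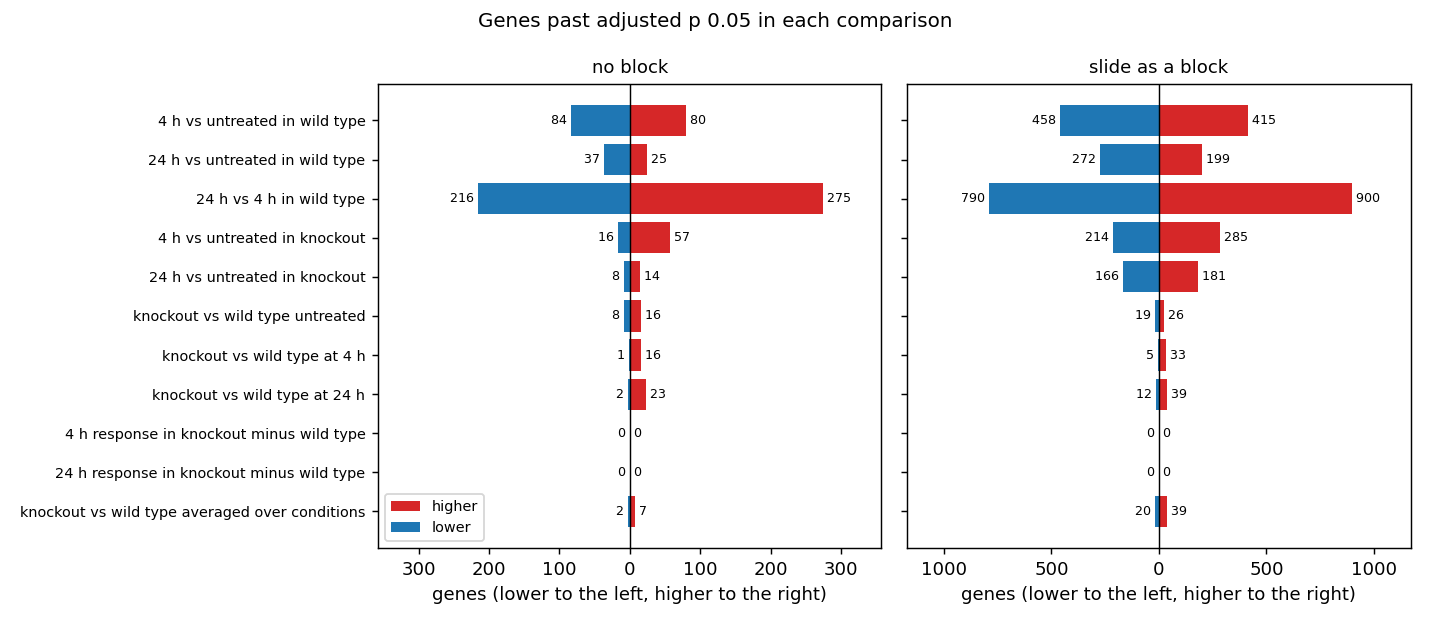
Number of genes past the threshold in each comparison (horizontal axis, lower to the left and higher to the right), with no block in the left panel and the slide as a block in the right panel. With no block 491 genes passed between 24 h and 4 h in wild-type cells, 24 between untreated genotypes and 0 for either difference in response.

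The genotypes were compared in untreated cells to ask which transcripts depend on Dnmt3a at rest. The complement gene C2 stood out. It was higher in knockout cells (log2 5.49 ± 0.35, 2 of 3, adjusted p = 5.43e-07), with a mean log2 intensity of 12.56 ± 0.36 (SD, n = 3) against 7.07 ± 0.44 and differences of 5.52, 5.14 and 5.82 on the 3 slides. The ribosomal protein gene copy Rps4l was higher (2.84 ± 0.23, 1 of 3, adjusted p = 1.06e-05), and the meiotic gene Syce1, part of the synaptonemal complex, was at least 5.15-fold higher (adjusted p = 0.00176). The homeobox gene Hoxb4, a regulator of blood stem cells, was at least 3.07-fold lower (adjusted p = 0.000937).

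Other genes higher in untreated knockout cells were Etl4 (at least 3.49-fold), the troponin gene Tnnt1 (1.99 ± 0.30, 2 of 3), the agouti pigment gene a (1.99 ± 0.26), Rapgefl1 (at least 2.78-fold), the germ cell gene Dnd1 (at least 2.78-fold), Noxred1 (at least 1.99-fold) and Lipo3 (1.34 ± 0.20). Lower were 6430548M08Rik (−2.20 ± 0.37, 2 of 3, adjusted p = 0.0119), the scaffold gene Iqgap2 (−1.48 ± 0.19), the secretion gene Cadps2 (−1.29 ± 0.18, 2 of 3), Sox12 (−1.26 ± 0.23; 1 of 2 other probes had the opposite sign), the cortisone reductase gene Hsd11b1 (−1.15 ± 0.22, 1 of 3), Socs5 (−0.96 ± 0.17) and Ccdc181 (−0.85 ± 0.17).

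Of 8 measured germline genes known to carry promoter methylation, Syce1 was higher in untreated knockout cells, 0 were lower, and the same count held when adjusted over the list alone. The list median was 0.23 (adjusted p = 0.00179; slides 0.08, 0.59 and 0.22), with adjusted p = 0.0495 with an estimated correlation and with no filter on dim probes a median of −0.01 over 43 genes (adjusted p = 0.496). Oxidative phosphorylation genes had a median of 0.18 (adjusted p = 1.01e-05; slides 0.07, 0.29 and 0.17; adjusted p = 0.407 with an estimated correlation). Ribosome production genes had a median of 0.13 (adjusted p = 0.01; slides 0.02, 0.21 and 0.13; adjusted p = 0.929 with an estimated correlation, 0.456 without knockout culture 6 and 0.765 without wild-type culture 8). Inhibitors of cytokine and receptor signalling had a median of −0.17 (adjusted p = 0.031; slides −0.15, −0.42 and −0.01; adjusted p = 0.299 with an estimated correlation). Without knockout cultures 4 and 6 and wild-type cultures 6 and 8 that list had adjusted p = 0.19, 0.0527, 0.0949 and 0.284. The cell cycle list rested on slide 2, with a median of 0.32 (adjusted p = 0.026; slides −0.24, 1.31 and −0.30; adjusted p = 0.929 with an estimated correlation), −0.05 (adjusted p = 0.936) without knockout culture 4 and 0.04 (0.765) without wild-type culture 8. These 4 lists had 0 genes past the threshold over all genes or over the list alone. Mast cell receptors had a median of −0.16 (adjusted p = 0.0687, and 0.0473 with the slide block).

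In untreated cells 24 genes passed limma's test between the genotypes, 16 higher and 8 lower in knockout cells, and 45 passed with the slide block (26 higher, 19 lower). Median scaling gave 7 genes, 6 higher and 1 lower, or 85.7% higher against 66.7%. The count was 10 without wild-type culture 8 and 13 without wild-type culture 9.

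At 4 h the same genotype differences were asked about in stimulated cells. C2 was again higher in knockout cells (5.14 ± 0.35, 2 of 3, adjusted p = 1.43e-06). Lta was higher (2.59 ± 0.40, 1 of 3, adjusted p = 0.00624), with a mean log2 intensity of 9.31 ± 0.97 (SD, n = 3) against 6.72 ± 0.61 and differences of 2.86, 1.84 and 3.08 on the 3 slides. Lgals7 was at least 5.45-fold higher (adjusted p = 0.0127), Ccn4 at least 3.73-fold (adjusted p = 0.0295), and the relaxin family gene Rln3 had 1.88 ± 0.26 (2 of 3, adjusted p = 0.00342). Rps4l (at least 6.43-fold), Syce1 (at least 4.31-fold), Tnnt1 (2.49 ± 0.30, 1 of 3), a (1.79 ± 0.26, 1 of 3) and Rapgefl1 (at least 2.50-fold) were higher and Hoxb4 was at least 2.57-fold lower. Csf2 had 1.59 ± 1.10 (adjusted p = 0.98) and Dusp2 2.48 ± 0.58 (1 of 3, adjusted p = 0.164).

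Of 24 cytokines, Lta was higher in knockout cells at 4 h, over all genes and when adjusted over the list alone, and 0 were lower. The list median was 0.29 (adjusted p = 0.000496) with 0.43, −0.08 and 0.81 on slides 1, 2 and 3, and adjusted p = 0.845 with an estimated correlation. Its adjusted p was 0.513 without knockout culture 3 and 0.625 without wild-type culture 9, where the median was 0.02. Immediate early genes had a median of 0.36 (adjusted p = 0.000496; slides 0.14, −0.03 and 0.75), with 0 past the threshold over all genes, 2 higher when adjusted over the list alone and adjusted p = 0.495 with an estimated correlation, 0.27 without knockout culture 3 and 0.449 without wild-type culture 9. All 8 germline genes had positive differences, with a median of 0.36 (adjusted p = 0.000324; slides 0.36, 0.42 and 0.35), Syce1 past the threshold over all genes and over the list alone, adjusted p = 0.0235 with an estimated correlation, and 0.993 with no filter on dim probes (median 0.01 over 43 genes). Oxidative phosphorylation genes (median 0.18, adjusted p = 5.89e-05; slides 0.01, 0.39 and 0.11) had adjusted p = 0.495 with an estimated correlation and 0.0915 without wild-type culture 8. Cell cycle genes (median 0.38, adjusted p = 0.00928; slides 0.04, 1.26 and −0.41) had adjusted p = 0.845 with an estimated correlation, 0.311 without knockout culture 4 and 0.859 without wild-type culture 8. Both had 0 genes past the threshold over all genes or over the list alone.

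At 4 h 17 genes passed limma's test between the genotypes, 16 higher and 1 lower in knockout cells, and 38 passed with the slide block (33 higher, 5 lower). Without wild-type cultures 8 and 9 the counts were 8 and 6.

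At 24 h the genotype comparison again showed C2 (4.89 ± 0.35, 1 of 3, adjusted p = 3.02e-06), Rps4l (at least 6.44-fold higher) and Syce1 (at least 5.63-fold higher). Lgals7 was at least 10.4-fold higher in knockout cells (adjusted p = 0.00129), with a mean log2 intensity of 10.08 ± 1.06 (SD, n = 3) against 6.34 ± 0.05, and Ccn4 was at least 4.52-fold higher (adjusted p = 0.00544). Eomes, a T-box factor of lymphocytes, had 2.13 ± 0.37 (2 of 3, adjusted p = 0.0183), Tnnt1 2.46 ± 0.30 and the zinc transporter gene Slc39a4 1.84 ± 0.34. Rapgefl1 (at least 2.76-fold) and a (at least 3.04-fold) were higher too, and Hoxb4 (at least 2.82-fold) and Sox12 (−1.22 ± 0.23, adjusted p = 0.0311) were lower. Csf2 had 2.22 (1 of 3, adjusted p = 0.999) and the stem cell factor receptor gene Kit −0.70 ± 0.31 (adjusted p = 0.958).

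List shifts between the genotypes at 24 h were small, and all of the following but germline genes had adjusted p = 0.744 with an estimated correlation and 0 genes past the threshold over all genes or over the list alone. Medians were 0.30 for cytokines (adjusted p = 0.000919; slides 0.53, 0.06 and 0.77), 0.36 for chemokines (0.0139; 0.21, 0.17 and 0.74), 0.09 for NF-kB genes (0.016; 0.04, 0.09 and 0.29) and 0.17 for ribosome production (0.0032; 0.19, −0.02 and 0.30). They were 0.16 for glycolysis (adjusted p = 0.0158; slides 0.11, 0.41 and 0.03), 0.11 for oxidative phosphorylation (0.0158; 0.08, 0.08 and 0.11) and −0.12 for mast cell receptors (0.0158; −0.06, −0.10 and −0.34). Germline genes had 0.26 (adjusted p = 0.00618; slides 0.20, 0.07 and 0.23), with Syce1 past the threshold over all genes and over the list alone adjusted p = 0.111 with an estimated correlation, and a median of −0.00 over 43 genes with no filter on dim probes (adjusted p = 0.481). Each of these 8 lists missed the threshold without at least 1 culture. Adjusted p-values were 0.0884 for cytokines without knockout 3, 0.118, 0.12, 0.096 and 0.0607 for chemokines and 0.192, 0.12, 0.107 and 0.0799 for NF-kB genes without knockout 3, knockout 6, wild-type 8 and wild-type 9. They were 0.346 and 0.412 for ribosome production and 0.212 and 0.162 for oxidative phosphorylation without knockout 6 and wild-type 6, and 0.201 and 0.096 for mast cell receptors without knockout 6 and wild-type 8. Germline genes had 0.0552 without wild-type 6. Glycolysis had 0.377, 0.187, 0.535 and 0.0999 without knockout 4, knockout 6, wild-type 6 (median −0.01) and wild-type 8. In limma 25 genes passed, 23 higher and 2 lower in knockout cells. The slide block gave 51 (39 and 12), array weights 504 (282 and 222). Without wild-type 6, 8 and 9 there were 12, 11 and 12.

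**Figure D3:**
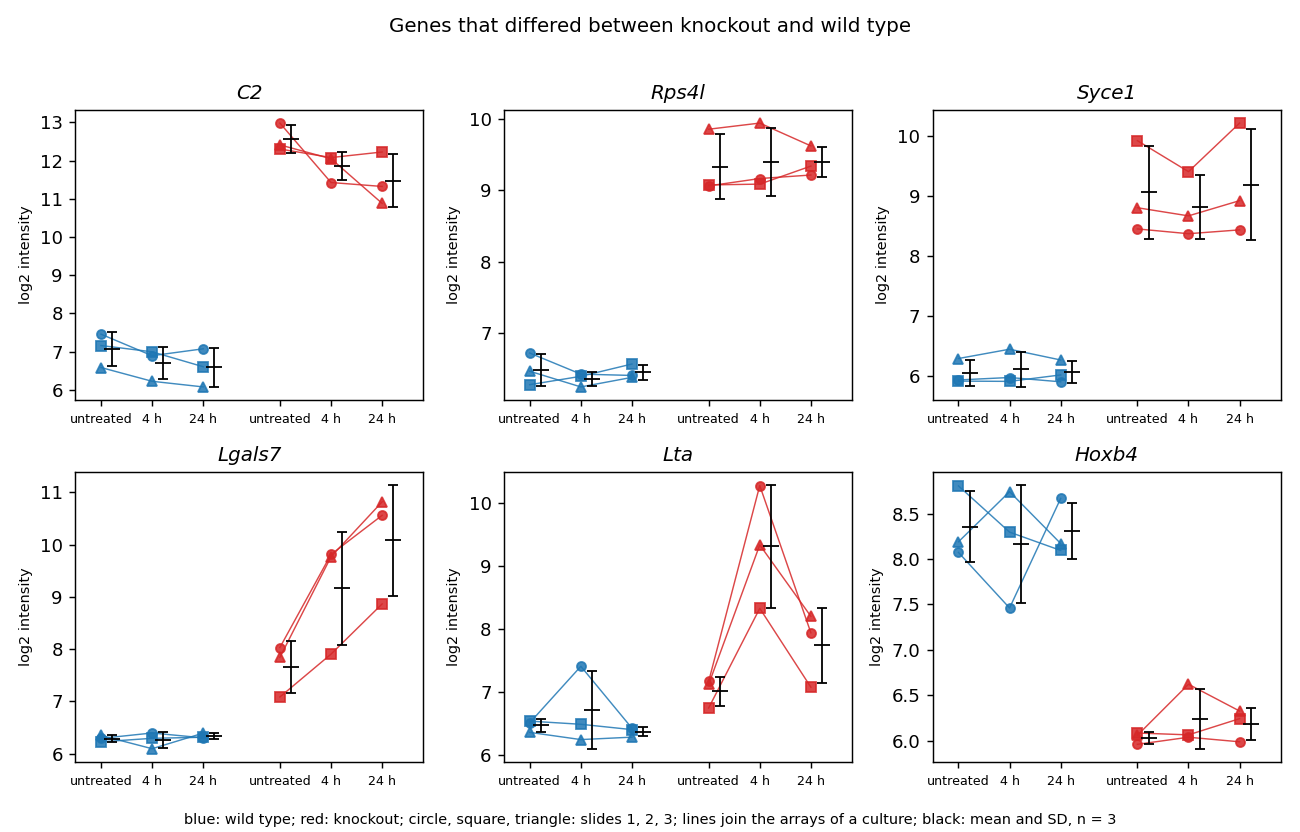
Log2 intensity (vertical axis) of C2, Rps4l, Syce1, Lgals7, Lta and Hoxb4 without stimulation and after 4 h and 24 h (horizontal axis), with wild-type cultures in blue, knockout cultures in red, symbols for slides 1, 2 and 3, lines joining a culture and black means ± SD (n = 3). C2 was at 12.56 in untreated knockout cells and 7.07 in wild-type cells.

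Over the 3 conditions, 37 genes differed between the genotypes in at least 1, 12 in all 3 and 20 in exactly 1. The 12 were C2, Rps4l, Syce1, Tnnt1, a, Rapgefl1, Etl4, Dnd1, Noxred1, Myo7a and Amhr2, all higher in knockout cells, and Hoxb4, which was lower. The difference had the same sign in all 3 conditions for 36 of the 37, the exception being Sucnr1, which was above the limit on 0 untreated and 0 of the 4 h arrays. When the arrays of a culture were averaged first, so that 3 knockout cultures were set against 3 wild-type cultures, 9 genes passed limma's test, 7 higher and 2 lower. Higher in knockout cells were C2 (adjusted p = 0.000788), Rps4l (0.00431), Dnd1 (0.0199), Tnnt1 (0.0373), Noxred1 (0.0373), the unconventional myosin gene Myo7a (0.0373) and Etl4 (0.0464), and lower were Hoxb4 (adjusted p = 0.00431) and 6430548M08Rik (0.0272). No sizes are given, since each was below the limit on at least 1 array of the lower genotype. Syce1 missed the threshold (adjusted p = 0.0516; 0.0366 with the slide block). The slide block gave 59 genes (39 higher, 20 lower). Without background correction there were 3 higher and 2 lower, or 60.0% higher against 77.8%. Without knockout cultures 3 and 6 there were 5 and 4 genes, and without wild-type cultures 6, 8 and 9 there were 4, 1 and 3.

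Averaged over conditions, 8 lists passed, each with 0 genes past the threshold over all genes and, but for germline genes, with adjusted p = 0.773 with an estimated correlation. Medians were 0.30 for cytokines (adjusted p = 0.00195; slides 0.37, −0.12 and 0.57; 1 gene higher when adjusted over the list alone), −0.20 for mast cell receptors (0.00439; −0.07, −0.20 and −0.19), 0.14 for chemokines (0.0393; 0.25, 0.00 and 0.66) and 0.12 for immediate early genes (0.0245; 0.02, 0.04 and 0.31). Oxidative phosphorylation had 0.15 (5.5e-06), the unfolded protein response 0.12 (0.0386) and ribosome production 0.08 (0.0245). Germline genes had 0.26 (adjusted p = 0.00172; slides 0.17, 0.33 and 0.21), with 1 gene higher when adjusted over the list alone adjusted p = 0.422 with an estimated correlation, and a median of −0.01 over 43 genes with no filter on dim probes (adjusted p = 0.875). Germline and oxidative phosphorylation genes stayed past the threshold without any 1 culture. Leaving out knockout culture 3 gave adjusted p = 0.534 for cytokines, 0.624 for chemokines, 0.539 for immediate early genes and 0.584 for the unfolded protein response, and leaving out wild-type culture 9 gave 0.367, 0.766, 0.383 and 0.766. Without knockout culture 6 chemokines had 0.0868, immediate early genes 0.0677 and ribosome production 0.947, and without knockout culture 4 the unfolded protein response had 0.0806. Without wild-type culture 8 there were 0.073 for mast cell receptors, 0.0578 for chemokines, 0.13 for immediate early genes and 0.0944 for ribosome production, which had 0.0717 without wild-type culture 6.

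The last comparisons asked whether the responses differed, by knockout minus wild-type response. For single genes, 0 passed limma's test at 4 h or 24 h. Unadjusted p was under 0.05 for 95 and 160, where 449.25 were expected by chance. So few point to a strict test and do not show equal responses. The 5 genes with the smallest p at 4 h were not past the threshold: Ppp1cb (−1.01 ± 0.18, adjusted p = 0.32), Rcan1 (1.09 ± 0.21, 0.393), Rsph3a (0.84 ± 0.23, 1), Rln3 (adjusted p = 0.842) and Lta (1). At 24 h they were Ppp1cb (−0.72 ± 0.18), Vps50 (−0.84 ± 0.23), Ccn4, Lgals7 and Sucnr1, each with adjusted p = 1. The genes without a size were above the limit on 0 untreated wild-type arrays. The slide block gave 0 genes at both times. With the replicate block 0 passed at 4 h and 1 at 24 h, Lgals7 (adjusted p = 0.0162). Without knockout culture 4 the count was 1 at both times, and with the culture as a random block it was 1 at 4 h.

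In all, 9 list results passed for a difference between the responses, each with 0 genes past the threshold. At 4 h the shift was larger in knockout cells for cytokines (median difference 0.40, adjusted p = 0.00164, positive for 19 of 24 genes, slides 0.24, 0.26 and 0.59), with adjusted p = 0.764 with an estimated correlation. No size is given for Csf2, which was above the limit on 0 untreated arrays. Immediate early genes had a median of 0.26 (adjusted p = 0.00164, 24 of 27 positive, slides 0.21, 0.02 and 0.68), with 1 higher when adjusted over the list alone and adjusted p = 0.734 with an estimated correlation. NF-kB genes had 0.22 (adjusted p = 0.0207; slides 0.29, 0.08 and 0.11; adjusted p = 0.764 with an estimated correlation) and interferon-stimulated genes 0.22 (adjusted p = 0.00356; slides 0.20, 0.37 and 0.09; adjusted p = 0.734 with an estimated correlation). Ribosome production genes had −0.19 (adjusted p = 0.000171; slides −0.10, −0.53 and −0.02; adjusted p = 0.764 with an estimated correlation) and the 5 macrophage markers 0.60 (adjusted p = 0.0402; slides 0.94, 0.19 and 0.40; adjusted p = 0.539 with an estimated correlation). At 24 h medians were 0.36 for cytokines (adjusted p = 0.00504; slides 0.31, 0.40 and 0.49), 0.25 for NF-kB genes (0.00504; 0.20, 0.32 and 0.39) and −0.44 for cell cycle genes (0.000886; −0.24, −1.14 and 0.02), each with adjusted p = 0.748 with an estimated correlation. Median scaling put the median of all genes at −0.13 in the 24 h comparison of responses.

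Each of these 9 differences between the responses missed the threshold without at least 1 culture. Without the 4 h array of wild-type culture 9, whose response was the smallest, the median for cytokines was 0.12 (adjusted p = 0.87), for immediate early genes 0.03 (0.775), for NF-kB genes 0.01 (0.87), for interferon-stimulated genes 0.31 (0.0551) and for macrophage markers 0.57 (0.246). Without the whole culture, adjusted p was 0.401 for cytokines, 0.476 for immediate early genes, 0.805 for NF-kB genes and 0.318 for macrophage markers. Without knockout culture 3 it was 0.0689 for cytokines, 0.0674 for immediate early genes, 0.196 for NF-kB genes, 0.0664 for interferon-stimulated genes and 0.194 for macrophage markers. NF-kB genes had 0.239 without knockout culture 4, macrophage markers 0.325 without wild-type culture 6, and without wild-type culture 8 interferon-stimulated genes had 0.235 and ribosome production 0.141. At 24 h, adjusted p without wild-type culture 8 was 0.0899 for cytokines, 0.0899 for NF-kB genes and 0.29 for cell cycle genes. It was 0.0886 for cytokines without knockout culture 6 and 0.581 for cell cycle genes without knockout culture 3. With all arrays kept, calls at 4 h ended too. With array weights adjusted p was 0.265 for cytokines, 0.282 for immediate early genes, 0.293 for NF-kB genes and 0.438 for macrophage markers. No filter gave 0.208 for cytokines (median 0.18), 0.331 for NF-kB genes, 0.0801 for interferon-stimulated genes and 0.0654 for macrophage markers, and mode-based detection gave 0.0831, 0.111, 0.0826 and 0.0936 for the same lists. Macrophage markers had 0.066 with cyclic loess, 0.0555 with no background correction or the authors' values and 0.0727 with fits to the compared groups alone.

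**Figure D4:**
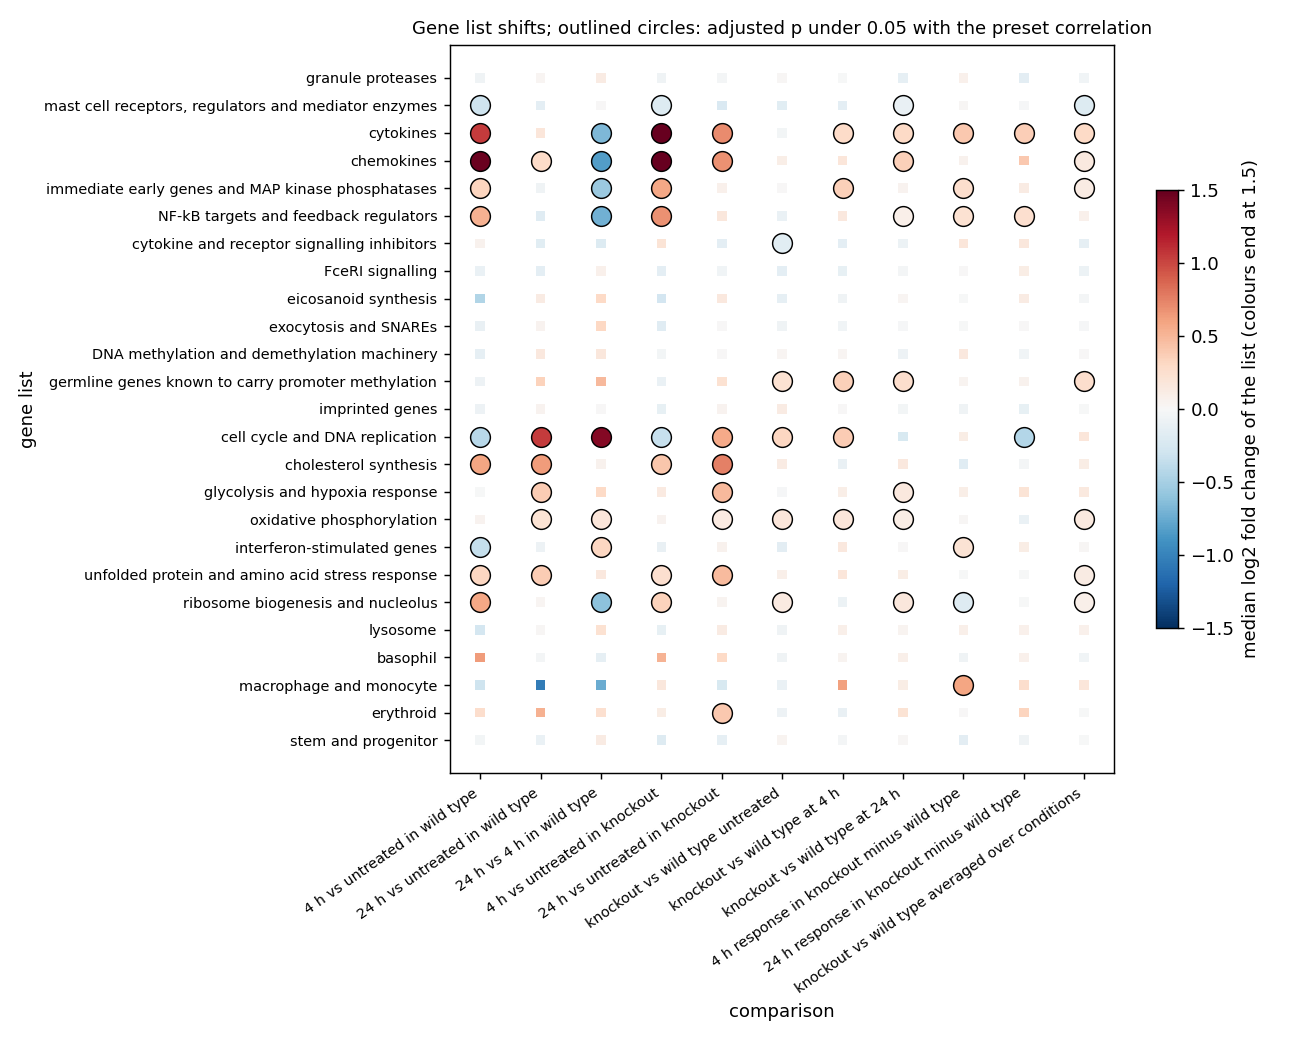
Median log2 fold change (colour, ending at 1.5 in either direction) of 25 gene lists (vertical axis) in 11 comparisons (horizontal axis), with outlined circles for lists with an adjusted p under 0.05 at the preset correlation. Cytokines had 1.04 at 4 h in wild-type cells and 1.51 in knockout cells.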

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

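The tests of DNA beside the Dnmt3a locus, of strain segments, of the small response of wild-type culture 9 and of genes varying together were chosen after the result was seen. No test of single samples far from the others was run within groups of 3 arrays.

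A test of the difference between the genotypes' responses singled out 9 list results. Median differences at 4 h were 0.40 (cytokines), 0.26 (immediate early), 0.22 (NF-kB), 0.22 (interferon-stimulated), −0.19 (ribosome production) and 0.60 (macrophage markers). At 24 h they were 0.36 (cytokines), 0.25 (NF-kB) and −0.44 (cell cycle). Probes without a gene name differed between genotypes too. Of 2596, 4 passed in untreated cells (3 higher and 1 lower in knockout) and 3 at 4 h (2 and 1). At 24 h 4 did (4 and 0). The slide block gave 10, 3 and 12.

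The first pattern is the 37 genes that differed between knockout and wild-type cells in at least 1 condition. DNA carried along beside the Dnmt3a locus, for which many of them should lie nearby, is argued against, since 0 of them were among the 100 measured genes nearest to Dnmt3a. Strain segments elsewhere stay open. Cfb, C2 and Lta lay together, with another of the 37 among the 20 measured genes on either side. Random sets had a median of 6 such genes against 3 (permutation p = 0.787, 10000 sets). So the total was not raised, but it cannot judge this group and would miss a segment with 1 such gene. A larger share of cells of another type in the knockout cultures cannot be told apart: at most 1 marker of a list was detected on at least 6 of 9 knockout and at most 3 of 9 wild-type arrays, but this count misses markers present in both genotypes, such as Mcpt8 and Adgre1 (9 and 9 arrays each), and Prss34 was on 9 and 6. An effect of the genotype itself stays open too, and single variants under a probe were not analysed.

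The next is the larger 4 h rise of the cytokine list in knockout cells, 0.400 in the median. Genes varying together could account for the call: with the correlation estimated (0.42, no block) the adjusted p was 0.764 against 0.00164. The smaller 4 h response of wild-type culture 9 and a genotype difference cannot be told apart. On slides 1 and 2 the median was 0.319 (list test, adjusted p = 0.210). Its 95% interval (0.0827 to 0.448) spans the bound of 0.200. Without only the 4 h array of that culture the median was 0.119 (95% interval −0.136 to 0.353, adjusted p = 0.87), and without the whole culture 0.189 (−0.00558 to 0.427, 0.401). A larger knockout response and the culture difference stay open. All intervals resample genes, not cultures.

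The third is that the cytokine list changed less from 4 h to 24 h in knockout culture 6 (median −0.58, against −0.94 and −1.10 in cultures 3 and 4, and −0.19 in wild-type culture 9 on the same slide), as did Il13 (−0.68 against −2.34 and −1.81) and Il6 (−0.28 against −1.55 and −1.35), but not Tnf (−2.70 against −2.70 and −1.11) or the chemokine Ccl2 (−0.94 against −1.21 and −0.79). A 4 h array under the 24 h label is argued against, because the change from 4 h to 24 h had a slope of 0.675 on that of wild-type cells, against 0.696 and 0.811 in cultures 3 and 4. RNA of the 4 h sample mixed into the 24 h sample cannot be told apart from a slower fall: transient genes outside the cytokine and chemokine lists kept 12.4% of their 4 h excess (95% interval 5.53 to 25.6, bound 18.2, 66 genes) where cytokines kept 36.4%. In cultures 3 and 4 transient genes kept −6.45% and −2.71% and cytokines 12.4% and 15.3%. No biological explanation was tested, since the design gives none for a single culture, and a feature of slide 3 stays open.

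Other splits of the samples were counted for each number of genes. With 3 samples against 3 there are 10 splits, too few for a share under 0.05. The real count and the highest of the other splits were 164 and 317 for 4 h in wild-type cells (2 of 10 splits as large as the real one), 62 and 0 for 24 h in wild-type cells (1), 491 and 0 for 24 h against 4 h (1), 73 and 0 for 4 h in knockout cells (1), and 22 and 1 for 24 h in knockout cells (1). Between genotypes they were 24 and 0 in untreated cells (1), 17 and 93 at 4 h (3), 25 and 2 at 24 h (1), and 9 and 3 for the culture means (1). For the difference in response they were 0 and 4 at 4 h (10) and 0 and 1 at 24 h (10). The split with 317 genes put the untreated and 4 h arrays of wild-type culture 6 with the 4 h array of culture 8, against the 4 h array of culture 9 and the other untreated arrays. The split with 93 put wild-type culture 6 with knockout cultures 3 and 4 at 4 h, against both slide 3 arrays and wild-type 8. Its count, several times the real one, points to a structure of the samples. Among the 4 splits that part all pairs, as the real one does, the highest other count was 0 in every comparison.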

How the results depend on the processing

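The alternatives without 1 array, on slides 1 and 2 alone and with mode-based detection were chosen after seeing the data. Signal over background limits what could be seen: 28.7% to 33.8% of the probes on an array were above the limit, and Dnmt3a was not. Named genes kept their direction in every setting run, at the probe chosen for each. Blocks, fits to the compared groups and leaving out an uncompared culture cannot change it. Among list results 1 reversed in the direction of its test, cell cycle and DNA replication between untreated genotypes without knockout culture 4 (median −0.052, fewer samples, and 0.56 at the most without another culture), and the median also changed sign with no filter on dim probes for germline genes (untreated −0.01, 24 h −0.00, averaged −0.01) and without wild-type culture 6 for glycolysis at 24 h (−0.01). For single named genes 3473 results stayed on their side of the threshold, 1281 were no longer past it, 10 became so and 0 reversed. The 76 list results past the threshold gave 1198 that stayed, 271 that were no longer past it and 1 that reversed, and lists not past it at first were not followed in these counts. The cause of the changes below was not tested, except that fits with fewer arrays or cultures have fewer samples and fits to the compared groups alone have fewer arrays behind the spread.

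In the order 4 h, 24 h and 24 h against 4 h in wild-type cells, then 4 h and 24 h in knockout cells, the counts of genes past the threshold were 164, 62, 491, 73 and 22. Between genotypes (untreated, 4 h, 24 h, culture means) they were 24, 17, 25 and 9, and for differences in response 0 and 0. Counts that moved by more than 1.5 times were the following. With the replicate block, the pairing by culture, they were 769, 418, 1606, 415 and 277 for time, and 1 for the 24 h difference in response. The slide block gave 873, 471, 1690, 499 and 347 for time and 45, 38, 51 and 59 for genotype. Every gene past the threshold with no block stayed past it with either block. The blocks ended list calls in knockout cells at 4 h alone, for mast cell receptors (adjusted p = 0.0539 by slide and 0.0509 by culture) and the cell cycle (0.0583 by slide). They brought 4 lists past the threshold: cytokines and macrophage markers at 24 h in wild-type cells with both blocks, signalling inhibitors from 4 h to 24 h with the replicate block and mast cell receptors between untreated genotypes with the slide block. The blocks changed no other list call. Genotype comparisons have no replicate block, since cultures differ between genotypes. The culture as a random block gave 822, 418, 1552, 507 and 309 for time and 1 for the 4 h difference in response. It and the fit to every kept probe gave no list test, and the random block gave no value for culture means.

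Median scaling gave 46, 19 and 44 in wild-type cells, 7 between untreated genotypes and 5 for culture means, and of the genes called without it 38, 13 and 43 were shared in wild-type cells. No background correction and the authors' values each gave 11 for knockout cells at 24 h and 5 for culture means. No filter gave 279 for 24 h against 4 h and 37 for knockout cells at 4 h. Every kept probe gave 5 for culture means. Mode-based detection gave 48 for knockout cells at 4 h. Fits to the compared groups alone gave 5, 39, 0 (2071 at an unadjusted p under 0.05), 43 and 9 for time and 9, 2 and 9 for genotype. Array weights gave 1551, 1283, 3533, 586 and 115 for time and 39, 57, 504 and 27 for genotype. Without the 4 h array of wild-type culture 9 the counts were 966 and 1413 in wild-type cells (4 h, and 24 h against 4 h) and 251 in knockout cells at 4 h. Without the 24 h array of knockout culture 6 there were 3 in knockout cells at 24 h. Slides 1 and 2 gave 473, 9, 900, 214 and 1 for time and 3, 2, 2 and 2 for genotype. The number of lists past the threshold was 76, and 2 with an estimated correlation. It was 91 with median scaling (71 of them among the 76), 65 with no filter (55) and 76 with array weights (59).

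List calls that ended in settings with every array kept had the following adjusted p-values, beside those in the report. With array weights these were at 4 h mast cell receptors (0.0831 in wild-type and 0.0664 in knockout cells), cytokines (0.407) and immediate early genes (0.23) between genotypes, and at 24 h glycolysis in wild-type cells (0.0507), oxidative phosphorylation in knockout cells (0.136) and between genotypes (0.0502), and ribosome production between genotypes (0.319). Averaged over conditions, array weights gave 0.34 for chemokines, 0.0997 for cytokines, 0.0979 for immediate early genes, 0.126 for ribosome production and 0.0997 for the unfolded protein response. No filter gave between genotypes 0.0619 for the cell cycle and for ribosome production (untreated), 0.132 for the cell cycle (4 h), and at 24 h 0.0674 for NF-kB genes, 0.0628 for glycolysis and for oxidative phosphorylation. In knockout cells at 24 h it gave 0.0891 for erythroid markers and 0.0685 for oxidative phosphorylation, and averaged over conditions 0.281 for chemokines, 0.103 for immediate early genes, 0.0904 for ribosome production and 0.103 for the unfolded protein response. Mode-based detection gave 0.145 for the cell cycle and 0.454 for germline genes (between genotypes at 4 h), 0.0604 for glycolysis (24 h, wild-type cells), 0.0765 for glycolysis (genotypes, 24 h) and 0.137 for erythroid markers (24 h, knockout cells). Averaged over conditions it gave 0.127 for germline genes, 0.0942 for chemokines, 0.0529 for immediate early genes and for ribosome production, and 0.0942 for the unfolded protein response. The cell cycle had 0.0816 between untreated genotypes with median scaling, and 0.0552 at 4 h in wild-type cells with no background correction or the authors' values. Cyclic loess gave 0.0816 for chemokines averaged over conditions and 0.0791 for oxidative phosphorylation from 4 h to 24 h, which had 0.0522 with fits to the compared groups alone.

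Leaving out each culture in turn gave 1 to 326 genes for 4 h in wild-type cells, 1 to 69 for 24 h, 1 to 683 for 24 h against 4 h, 16 to 154 for 4 h and 4 to 17 for 24 h in knockout cells. It gave 10 to 24 between untreated genotypes, 6 to 24 at 4 h, 11 to 28 at 24 h, 1 to 8 for culture means, and 0 to 1 for each difference in response. The number of lists past the threshold was between 68 and 88.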

Other observations

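Some markers of related cells were detected in both genotypes, others in neither. Basophil Mcpt8 and macrophage Adgre1 and Lyz1 were above the limit on 9 of 9 knockout and 9 of 9 wild-type arrays. Lyz2 was on 6 and 6 and Apoe on 1 and 7. Basophil Itga2 and Itgam and macrophage Mrc1, C1qa and Mpeg1 were on 0 and 0.

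Response sizes differed. As a slope on the other genotype's changes, the 4 h response was 1.0, 1.02 and 0.455 in wild-type cultures 6, 8 and 9 and 0.979, 0.940 and 0.747 in knockout cultures 3, 4 and 6. At 24 h the slopes were 0.952, 0.658 and 0.602 in wild-type and 0.875, 0.638 and 0.851 in knockout cultures. Of unnamed probes, 6, 8 and 24 passed in wild-type cells (4 h, 24 h, 24 h against 4 h). In knockout cells 0 and 8 did, and 2 for culture means. The slide block gave 143, 104, 220, 156, 151 and 31.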
